A study of Arabidopsis thaliana with 12 samples.

How the data were processed

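RNA was measured in 12 libraries from rosette leaves of Arabidopsis thaliana, 3 for each of 4 groups: wild type (Col-0) and the PAD4 knockout (pad4), each after 2'cADPR or after water. Per the labels, total RNA was extracted with TRIzol and made into libraries with a SMARTER mRNA-seq kit. Groups were taken from the sample titles and labels; samples titled mock had received water per the labels. The dose, the time after treatment and the age of the plants are not given in the sources used here.

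The deposited count table holds raw counts of reads per gene, whole numbers with a different total in each library. The deposited FPKM table holds counts scaled by gene length and library total, which the authors computed from the same counts: count, gene length and the table's library total gave back the FPKM. The 24 files per sample were checked and equalled their columns of these tables (24 of 24), so the tables alone were used. The submitters' processing notes name fastp, HISAT and HTSeq and the genome build TAIR10; versions and settings are not given in the sources used here. Gene lengths implied by the FPKM matched the summed exon lengths of the TAIR10 reference for 24224 of 24228 genes (99.98%), so reference coordinates were used. Whether counting took the strand into account is not given in the sources used here, which leaves overlapping antisense genes uncertain. Reads of near-identical copies, such as those of LHCB1, the Rubisco small subunits, GSTF6 and GSTF7, AOC1 and AOC2, KIN1 and KIN2, COR15A and COR15B, and EDS1 and EDS1B, may have been shared or lost between copies.

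The table held 24228 genes: 22701 protein-coding and 1527 long noncoding, among them 81 chloroplast and 26 mitochondrial genes. Library totals lay between 35.8 and 44.4 M counts. The 10 most abundant genes took 4.81% to 6.61% of a library, and chloroplast genes at most 0.0535%. After edgeR's filterByExpr by group with a minimum count of 10, 19652 genes were tested, which kept 99.98% of all counts. The median standard error of a log2 fold change was 0.120 in wild type, 0.117 in pad4 and 0.168 for the interaction.

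Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM factors, a quasi-likelihood fit of all 12 libraries with a mean for each group, and two-sided F-tests. The 5 comparisons were 2'cADPR against water in wild type, the same in pad4, the difference between these responses (the interaction, pad4 minus wild type), pad4 against wild type after water, and pad4 against wild type after 2'cADPR. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. CPM are counts scaled to TMM-adjusted library totals. The PAD4 level was compared by an exact two-sided permutation of log2 CPM with 0.5 added, 6 libraries against 6.

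In all, 24 gene lists with 440 genes were written from general knowledge before the data were examined, as were the tests, the rule for naming genes and the alternatives listed first below; 433 of the genes were in the table and 7 were not. The lists covered the EDS1 module with its PAD4, SAG101, ADR1 and NRG1 partners, salicylic acid, pathogenesis and systemic acquired resistance, TIR-domain receptors, pattern-triggered immunity, WRKY factors, camalexin and indole glucosinolates, jasmonate, ethylene, cysteine-rich receptor-like kinases, calcium, negative regulators of immunity, endoplasmic reticulum chaperones, detoxification, heat shock, abscisic acid, photosynthesis, auxin and cell expansion, senescence and the circadian clock, and markers of epidermis, guard cells, vascular tissue, and flower, seed and root. Each was tested with camera from limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the 24 lists of a comparison. Members were also adjusted over the list alone. The EDS1 module list includes PAD4, the gene knocked out in pad4. Lists could share genes: DMR6, DLO1, NPR3 and NPR4 are both in the salicylic acid list and among the negative regulators. Several WRKY genes are in both the salicylic acid and WRKY lists. Camera with the correlation estimated per list and fry were the alternatives.

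Named genes were chosen by rule: PAD4; EDS1, SAG101, ADR1, ADR1-L1, ADR1-L2, ICS1, PR1 and FMO1; in each comparison the 5 genes with the largest rise and the 5 with the largest fall among called genes with a symbol, at least 5 CPM in the higher group and no overlap between the replicates of the groups (not asked of the interaction); and for each list up to 4 members with the smallest adjusted p in the list's direction, or up to 2 called members of a list that did not pass. Any other gene is said to be chosen after its values were seen. Where a group had no reads, a fold is a lower bound against 3 counts over the group. Where it had 1 to 3 reads, the ratio is given with its 95% Poisson interval.

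The alternatives set before the data were examined were DESeq2 1.42.0 with default settings, RLE factors in edgeR, no filter on low counts, a filter of at least 5 CPM in at least 3 libraries, the replicate number as a block, a fit of only the compared groups, limma-voom, limma-trend on log2 of FPKM with 1 or 0.1 added, an absolute log2 fold change of at least 1, and each library left out in turn. Added after seeing the data were runs without scaling factors, with every library thinned to the smallest total, with trends on GC content and length removed, and camera without water-treated wild type library 1. Strand-specific and splicing questions were not analysed here.

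The procedure was tested on simulated data made from these counts, with 19268 genes and 3 libraries per group. At a 1.5-fold change edgeR found 70% of changed genes in the wild type comparison, 64% in the pad4 comparison and 41% for the interaction. Each gene was given the same spread in all groups, and different genes were changed in each genotype. At 2-fold it found 92%, 76% and 72%, and at 4-fold 100%, 98% and 99%. False calls were 7 of 147, 6 of 135 and 8 of 227. In each genotype 50 genes were changed at each fold, all with at least 1 CPM in water-treated libraries of both genotypes. The adjusted threshold depends on how many genes change, so these shares do not carry over directly to the data. Camera called 1 of 20 unchanged simulated lists (adjusted p = 0.0320) and the raised list. Genes were simulated independently and the lists drawn at random, so this could not test camera where genes of a list are correlated.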

Results

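Messenger RNA was sequenced from rosette leaves of Arabidopsis thaliana that had received either 2'cADPR or water. The compound 2'cADPR is an isomer of cyclic ADP-ribose made by TIR-domain immune proteins. The plants were wild type, of the accession Col-0, or carried a knockout of PAD4, called pad4 here; PAD4 encodes a lipase-like partner of EDS1 that signals with the helper receptor ADR1. The study asked what 2'cADPR does and whether its action depends on the EDS1-PAD4-ADR1 pathway. The 4 groups of genotype and treatment held 3 libraries each, 12 in all. Library totals ran from 35.8 to 44.4 M (1e6) counted reads, with group means of 39.4 ± 3.92 M in wild type after water, 43.0 ± 1.35 M in wild type after 2'cADPR, 42.5 ± 0.375 M in pad4 after water and 43.0 ± 0.778 M in pad4 after 2'cADPR (SD, n = 3). The table held 24228 genes, of which 19652 had enough counts to be tested. Spearman correlations between libraries of the same group lay between 0.992 and 0.996 across genes, which are not independent replicates. On the first principal component, which held 81.1% of the variance, the treated wild type libraries lay between 155 and 168, the water-treated wild type libraries between -13.0 and 11.6, and all pad4 libraries between -84.5 and -76.4. Levels below are in CPM, read counts per 1e6 of scaled library total, given as mean ± SD of 3 libraries. The labels do not say that replicates came from separate plants or harvests, so p-values measure the spread between these samples, which may be technical.

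PAD4 transcript was low in every pad4 library. PAD4 (AT3G52430), at chromosome 3 from 19431095 to 19434450 on the plus strand of TAIR10 with 2255 bases of exon, stood at 68.6 ± 5.78 CPM in wild type after water and 552 ± 36.0 CPM after 2'cADPR (SD, n = 3). In pad4 it stood at 3.86 ± 1.43 and 3.45 ± 1.196 CPM, which is 5.64% and 0.624% of the wild type level after the same treatment. Across the 6 libraries of each genotype, log2 CPM with 0.5 added differed by -5.60 (exact two-sided permutation p = 0.00216, the smallest that the 924 splits can give). Each pad4 library held 114 to 237 PAD4 reads, so remaining transcript was measured well above a count of 0.

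**Figure D1:**
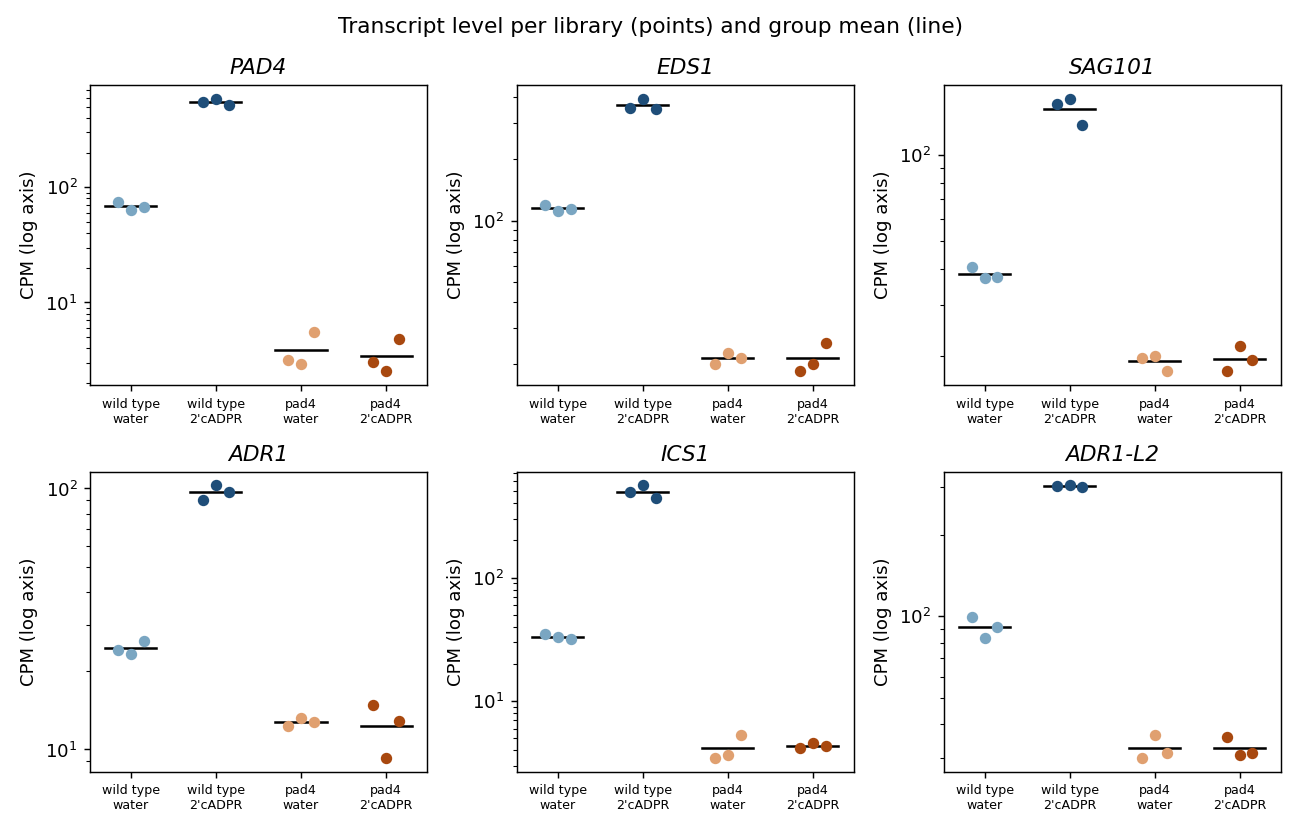
CPM on a log axis of PAD4, EDS1, SAG101, ADR1, ICS1 and ADR1-L2 in each library of the 4 groups, with points for libraries and a line for the group mean. Each gene is highest in wild type after 2'cADPR, and the treated and water-treated pad4 libraries overlap.

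In wild type, 2'cADPR raised many genes of plant immunity and lowered many of growth and photosynthesis. As groups, 0 of the 24 gene lists written before the data were examined passed camera's test with an estimated correlation (lowest adjusted p = 0.135). FMO1 (AT1G19250), which makes the systemic defence signal N-hydroxypipecolic acid, rose from 0.395 ± 0.137 to 50.6 ± 1.62 CPM (SD, n = 3; log2 fold change 7.01, adjusted p = 3.07e-11). ICS1 (AT1G74710), the main enzyme of salicylic acid synthesis under attack, rose from 33.3 ± 1.42 to 497 ± 57.7 CPM (log2 3.90, adjusted p = 7.06e-12). The auxin response repressor IAA3 (AT1G04240) fell from 45.7 ± 1.44 to 5.60 ± 0.668 CPM (log2 -3.03, adjusted p = 1.45e-11), and the Rubisco small subunit gene RBCS2B (AT5G38420) fell from 3228 ± 259.9 to 612 ± 79.4 CPM (log2 -2.40, adjusted p = 5.88e-11). In all 13608 of 19652 tested genes changed, or 69.2%, with 6809 up and 6799 down. Of these, 2510 rose and 3492 fell at least 2-fold.

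The largest rises among genes with at least 5 CPM in the higher group were in WRKY59 (AT2G21900), FMO1, ALD1 (AT2G13810), XTH10 (AT2G14620) and ARD3 (AT2G26400). WRKY59 rose from 0.0867 ± 0.0560 to 11.7 ± 3.34 CPM. ALD1, an aminotransferase of pipecolic acid synthesis, rose from 0.379 ± 0.244 to 46.8 ± 4.01 CPM. XTH10, a xyloglucan enzyme of the cell wall, rose from 0.444 ± 0.147 to 50.3 ± 7.03 CPM, and ARD3, of methionine salvage, rose from 7.63 ± 5.92 to 604 ± 73.9 CPM. Their log2 fold changes were 7.03 for WRKY59, 6.96 for ALD1, 6.82 for XTH10 and 6.32 for ARD3. The largest falls were in GASA6 (AT1G74670), a gibberellin-regulated peptide gene (-6.83), XTH31 (AT3G44990), another xyloglucan enzyme (-6.76), BZIP34 (AT2G42380) (-6.18), HAT1 (AT4G17460), a homeodomain regulator (-5.48), and PDLP3 (AT2G33330), a plasmodesmal protein (-5.40). XTH31 fell from 69.8 ± 9.66 to 0.644 ± 0.180 CPM and GASA6 from 18.4 ± 4.06 to 0.159 ± 0.154 CPM. Some values moved with a single library. Without water-treated wild type library 1 the log2 change was 7.61 for ALD1 and 7.16 for ARD3, without treated library 1 it was -7.94 for GASA6, and without treated library 3 it was -6.86 for HAT1.

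Of the 24 lists 16 passed camera's test with its preset correlation in wild type, and 0 passed with an estimated correlation. Fry passed 22, but it asks whether a list's genes move on balance, not whether they move more than other genes. In the EDS1-PAD4-ADR1 and EDS1-SAG101-NRG1 module, 8 of 9 genes rose and 9 did when adjusted over the list alone (median log2 1.68; camera adjusted p = 1.21e-06, adjusted p = 0.152 with an estimated correlation). EDS1 (AT3G48090) rose from 115 ± 4.04 to 367 ± 23.7 CPM, SAG101 (AT5G14930) from 38.6 ± 1.93 to 144 ± 15.3 CPM, and the helper receptor genes ADR1-L1 (AT4G33300) from 184 ± 16.9 to 559 ± 28.1 CPM and ADR1-L2 (AT5G04720) from 91.2 ± 7.93 to 303 ± 1.64 CPM. ADR1 (AT1G33560) rose from 24.4 ± 1.397 to 96.9 ± 6.10 CPM and PAD4 itself by a log2 of 3.01. EDS1 has a near-identical neighbour, so its reads could be shared with that copy. Of 22 genes of salicylic acid synthesis and signalling 21 rose, and 21 adjusted over the list alone (median log2 2.41; camera adjusted p = 1.11e-11, adjusted p = 0.135 with an estimated correlation). Among them CBP60g (AT5G26920), a regulator of ICS1, rose from 34.7 ± 6.19 to 562 ± 75.4 CPM, PBS3 (AT5G13320) from 20.6 ± 3.02 to 454 ± 72.5 CPM and the salicylic acid receptor NPR3 (AT5G45110) from 38.4 ± 5.12 to 336 ± 45.5 CPM. Of 10 negative regulators of immunity and cell death 9 rose and 1 fell, the same numbers as adjusted over the list alone (median log2 1.82; camera adjusted p = 3.05e-06, adjusted p = 0.135 with an estimated correlation). The Nudix hydrolase gene NUDT7 (AT4G12720) had a log2 of 2.43 and NUDT6 (AT2G04450) of 4.41.

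Genes of pathogenesis and systemic acquired resistance rose in 11 of 17 cases, also 11 adjusted over the list alone (median log2 1.89; camera adjusted p = 2.55e-06, adjusted p = 0.152 with an estimated correlation). SARD4 (AT5G52810), of pipecolic acid synthesis, rose from 74.9 ± 7.78 to 409 ± 24.4 CPM and PNP-A (AT2G18660) from 6.90 ± 1.01 to 205 ± 33.8 CPM. PR1 (AT2G14610), a widely used marker of salicylic acid responses, stood at 11.8 ± 16.7 CPM after water, with 31.1 CPM in library 1 and 1.94 and 2.48 CPM in the others, and at 307 ± 48.6 CPM after 2'cADPR (log2 4.71, or 7.13 without that library). Among the TIR-domain receptors 21 of 27 rose and 2 fell, and 21 and 2 adjusted over the list alone (median log2 0.79; camera adjusted p = 2.80e-06, adjusted p = 0.203 with an estimated correlation). RPP4 (AT4G16860) rose from 172 ± 14.4 to 577 ± 38.8 CPM and TN10 (AT1G72900) from 48.4 ± 6.75 to 204 ± 8.43 CPM. In pattern-triggered immunity 23 of 26 rose and 2 fell, the same adjusted over the list alone (median log2 1.41; camera adjusted p = 3.29e-06, adjusted p = 0.220 with an estimated correlation). The co-receptor gene BAK1 (AT4G33430) had a log2 of 1.51 and XLG2 (AT4G34390) of 1.96. WRKY transcription factors rose in 28 of 31 cases, 28 adjusted over the list alone (median log2 1.95; camera adjusted p = 1.29e-07, adjusted p = 0.203 with an estimated correlation). WRKY46 (AT2G46400) rose from 30.6 ± 4.79 to 334 ± 38.4 CPM. Of the cysteine-rich receptor-like kinases 20 of 23 rose and 2 fell, the same adjusted over the list alone (median log2 1.30; camera adjusted p = 2.15e-05, adjusted p = 0.256 with an estimated correlation). CRK13 (AT4G23210) rose from 101 ± 20.7 to 1076 ± 147 CPM. Of the calcium signalling genes 11 of 14 rose and 1 fell, the same adjusted over the list alone (median log2 1.99; camera adjusted p = 7.23e-04, adjusted p = 0.203 with an estimated correlation). The calcium pump gene ACA13 (AT3G22910) rose from 16.0 ± 2.06 to 519 ± 89.9 CPM.

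Stress and secretion genes rose as well. Of 17 genes for endoplasmic reticulum chaperones and secretion 16 rose and 1 fell, the same adjusted over the list alone (median log2 1.30; camera adjusted p = 4.68e-09, adjusted p = 0.203 with an estimated correlation). BZIP60 (AT1G42990), a regulator of the unfolded protein response, rose from 78.5 ± 12.4 to 308 ± 30.9 CPM and the chaperone gene BIP2 (AT5G42020) from 683 ± 84.8 to 2243 ± 188 CPM. In detoxification and oxidative stress 14 of 17 rose and 2 fell, the same adjusted over the list alone (median log2 1.71; camera adjusted p = 1.42e-04, adjusted p = 0.220 with an estimated correlation). The glutathione transferase gene GSTF8 (AT2G47730) rose from 544 ± 20.1 to 1780.0 ± 62.7 CPM. In the heat shock response 9 of 16 rose and 1 fell, the same adjusted over the list alone (median log2 0.69; camera adjusted p = 0.0272, adjusted p = 0.335 with an estimated correlation). HSFB1 (AT4G36990) had a log2 of 2.41. In camalexin and indole glucosinolate synthesis 16 of 22 rose and 2 fell, the same adjusted over the list alone (median log2 0.78; camera adjusted p = 0.00928, adjusted p = 0.368 with an estimated correlation). The regulator MYB51 (AT1G18570) had a log2 of 2.08. The senescence list did not pass camera's test, although 7 of 11 genes rose and 1 fell, and 8 and 1 adjusted over the list alone (median log2 1.43; camera adjusted p = 0.110). Jasmonate genes split, with LOX4 (AT1G72520) at a log2 of 2.36 and TAT3 (AT2G24850) at 3.19 among 9 of 25 genes that rose, and 6 that fell, the same adjusted over the list alone (median log2 0.21; camera adjusted p = 0.473). Ethylene genes had 8 of 16 up and 3 down, the same adjusted over the list alone (median log2 0.54; camera adjusted p = 0.161). In the circadian clock list 6 of 20 rose and 6 fell, the same adjusted over the list alone. The median log2 was 0.042 and the mean 0.22, while camera's direction was down (adjusted p = 0.843).

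Growth and photosynthesis genes fell in wild type. Of 28 photosynthesis genes 24 fell and 1 rose, the same adjusted over the list alone (median log2 -0.80; camera adjusted p = 2.49e-05, adjusted p = 0.433 with an estimated correlation). Near-identical members of this list, such as the Rubisco small subunit genes, could share reads. Of 17 genes of auxin and cell expansion 14 fell and 1 rose, the same adjusted over the list alone (median log2 -1.62; camera adjusted p = 2.42e-04, adjusted p = 0.203 with an estimated correlation). The expansin genes, whose products loosen cell walls, fell from 122 ± 31.4 to 9.61 ± 1.80 CPM for EXPA1 (AT1G69530) and from 77.8 ± 18.1 to 4.41 ± 0.308 CPM for EXPA8 (AT2G40610). In the abscisic acid and water stress list 10 of 19 fell and 5 rose, the same adjusted over the list alone (median log2 -0.73; camera adjusted p = 0.125). The cold- and drought-induced COR15B (AT2G42530) fell from 535 ± 44.0 to 62.7 ± 11.8 CPM. Among the markers of other cell types, only the epidermis list passed camera's test. Epidermis markers fell in 8 of 10 cases, 8 adjusted over the list alone (median log2 -1.30; camera adjusted p = 0.00246, adjusted p = 0.324 with an estimated correlation). CER3 (AT5G57800), of wax synthesis, fell from 112 ± 9.47 to 36.1 ± 2.70 CPM. Guard cell markers had 2 of 10 up and 3 down, the same adjusted over the list alone (median log2 -0.054; camera adjusted p = 0.622). Vascular markers had 6 of 14 down, 6 adjusted over the list alone (median log2 -0.30; camera adjusted p = 0.488). Of the 4 flower, seed and root markers that could be tested 2 were down, 2 adjusted over the list alone (median log2 -0.93; camera adjusted p = 0.622).

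Some members moved against their list in wild type; those below were chosen after their values were seen, with log2 fold changes in parentheses. Rises were measured for LHCB1.4 (AT2G34430) (0.69) of the photosynthesis list and GH3.6 (AT5G54510) (1.82) of the auxin list. Falls were measured for MYB34 (AT5G60890) (-4.45) of the indole glucosinolate list, PROPEP1 (AT5G64900) (-1.47) of pattern-triggered immunity, RBA1 (AT1G47370) (-1.36) of the TIR-domain receptors, ANN4 (AT2G38750) (-2.29) of calcium signalling and HSP18.2 (AT5G59720) (-2.36) of the heat shock list. In the jasmonate list falls were measured for LOX2 (AT3G45140) (-0.999), AOS (AT5G42650) (-1.13) and MYC2 (AT1G32640) (-0.29). In the abscisic acid list RD29B (AT5G52300) (1.94) rose, whereas KIN1 (AT5G15960) (-2.45) fell with its list.

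In pad4, the treated and water-treated leaves differed at a single gene by edgeR. FAMT (AT3G44860), a methyltransferase that acts on farnesoic acid, rose from 14.3 ± 2.01 to 29.8 ± 4.39 CPM (SD, n = 3; log2 1.05, adjusted p = 0.00289). It lies on chromosome 3 from 16379571 to 16381434. In wild type FAMT rose from 44.8 ± 1.496 to 96.0 ± 5.77 CPM, a log2 of 1.099, and its response did not differ between genotypes (interaction adjusted p = 0.817). ICS1 stood at 4.17 ± 1.03 CPM after water and 4.37 ± 0.213 CPM after 2'cADPR, EDS1 at 21.3 ± 1.26 and 21.2 ± 3.67 CPM, and ADR1-L1 at 55.4 ± 2.37 and 55.4 ± 1.17 CPM; their adjusted p were 0.998, 1 and 1. The log2 changes were 0.028 for SAG101, -0.050 for ADR1, 7.4e-04 for ADR1-L2 and -0.17 for PAD4, none of which passed. FMO1 stood at 0.1001 ± 0.0804 CPM after water and at 0 in each treated pad4 library, and PR1 had 0 to 8 counts in each pad4 library. Unadjusted p was under 0.05 for 992 genes, where chance gives 983. This number depended on the fit: it was 1335 of 18870 with only the pad4 groups in the fit, and 773 of 19927 without treated pad4 library 3. DESeq2 called 26 genes and limma-voom 1, and edgeR called 2 without water-treated pad4 library 1 and 3 without library 3.

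Of the 24 lists, those for jasmonate and for abscisic acid and water stress passed camera's test in pad4, and neither did with an estimated correlation. No jasmonate gene was called over all genes, and 11 of 25 rose and 2 fell adjusted over the list alone (median log2 0.39; camera adjusted p = 5.39e-15, adjusted p = 0.185 with an estimated correlation). The median was 0.24 without water-treated pad4 library 2 and 0.63 without library 1, and another split of the pad4 libraries gave an absolute median of 0.48 where the real one gave 0.43. The lipoxygenase gene LOX2 went from 1751 ± 199 to 2395 ± 372 CPM, the jasmonate response regulator MYC2 from 124 ± 13.0 to 176 ± 19.8 CPM, and the storage protein gene VSP2 (AT5G24770) from 38.9 ± 13.4 to 87.4 ± 36.1 CPM, all chosen after their values were seen. The list adjusted p were 0.0319, 0.00145 and 0.0204. In the abscisic acid and water stress list 0 of 19 genes passed over all genes or adjusted over the list alone (median log2 0.24; camera adjusted p = 2.38e-04, adjusted p = 0.9999 with an estimated correlation). For the salicylic acid list the median log2 was 0.062 (camera adjusted p = 0.168), for pattern-triggered immunity 0.034 (0.263), for photosynthesis -0.037 (0.158) and for epidermis markers 0.044 (0.451). For pathogenesis and systemic acquired resistance the median was 0.16 and the mean -0.36, with FMO1 down adjusted over the list alone (camera adjusted p = 0.535). That mean includes fitted values of FMO1 and ALD1, with 13 and 2 reads over water-treated pad4 and 0 over treated pad4. The mean and the FMO1 call thus rest in part on very few reads. Fry, which asks whether a list's genes move on balance, passed 0 lists.

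The response to 2'cADPR differed between wild type and pad4 for many genes of immunity, growth and photosynthesis. As groups, 0 of the 24 lists passed for this difference with an estimated correlation (lowest adjusted p = 0.168). The interaction is the log2 change in pad4 minus that in wild type. For ICS1 it was -3.84 ± 0.185 (SE, adjusted p = 1.29e-09), with a rise from 33.3 ± 1.42 to 497 ± 57.7 CPM in wild type against 4.17 ± 1.03 and 4.37 ± 0.213 CPM in pad4. For EDS1 it was -1.69, for SAG101 -1.87, for ADR1 -2.04, for ADR1-L1 -1.60, for ADR1-L2 -1.73 and for PAD4 -3.18. For IAA3, which fell in wild type, it was 3.08 (adjusted p = 6.87e-10), and for RBCS2B 2.17 (adjusted p = 1.15e-08). In all 11326 of 19652 genes had a response that differed, 5787 with a higher and 5539 with a lower change in pad4, and 11174 of the 13608 genes called in wild type were among them (82.1%). At least 2-fold differences were found in 5336 genes.

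Among called genes that met the naming rule, the most negative fitted interactions were in FMO1, ALD1, CHX17 (AT4G23700), CML43 (AT5G44460) and ABCB11 (AT1G02520). FMO1, ALD1, the cation exchanger gene CHX17 and the calmodulin-like gene CML43 had no reads in pad4 after 2'cADPR, so no fold is given; their adjusted p were 1.22e-06, 0.00831, 0.00748 and 0.00471. In wild type CHX17 rose from 0.740 ± 0.635 to 13.8 ± 2.40 CPM and CML43 from 0.314 ± 0.239 to 6.995 ± 0.719 CPM. ABCB11, a transporter gene, had an interaction of -6.33 ± 0.586 (SE), rising from 0.331 ± 0.128 to 23.9 ± 3.65 CPM in wild type. Calls for some of these rested on few reads of a single library: without water-treated pad4 library 1 the adjusted p was 0.9998 for ALD1 and 0.267 for CHX17, and without library 3 it was 0.9998 for CML43. Over all alternatives the adjusted p ran from 5.20e-10 to 0.9998 for ALD1, from 1.01e-06 to 0.267 for CHX17 and from 1.62e-07 to 0.9998 for CML43. In water-treated pad4 ALD1 held 2 reads, CHX17 10 and CML43 6 over the group. The lost calls thus bear on the change within pad4, not on the rises in wild type. The largest positive interactions were in CSLA01 (AT4G16590), TPS03 (AT4G16740), IAA29 (AT4G32280), HMT3 (AT3G22740) and MYB47 (AT1G18710). CSLA01, a mannan synthase, and TPS03, a terpene synthase, had at most a single read in treated wild type (adjusted p = 2.65e-05 and 6.28e-05). The interaction was 7.12 for IAA29, 6.79 for the methyltransferase gene HMT3 and 6.76 for MYB47. Without treated wild type library 3 that group had no IAA29 reads (adjusted p = 5.24e-06), and without library 1 it had 3 HMT3 reads (adjusted p = 2.80e-08). PR1 did not pass (adjusted p = 0.437), and passed without water-treated wild type library 1 (adjusted p = 0.00120; range over alternatives 1.88e-04 to 0.954).

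Of the 24 lists 17 passed camera's test for the interaction, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.168. Fry, which does not compare a list with other genes, passed 21. In the salicylic acid list 18 of 22 genes had a lower change in pad4, 18 adjusted over the list alone (median log2 -2.54; camera adjusted p = 1.88e-10, adjusted p = 0.168 with an estimated correlation). The value was -3.02 for NPR3 and -3.73 for WRKY46. In the EDS1 module 8 of 9 did, 8 adjusted over the list alone (median log2 -1.69; camera adjusted p = 1.06e-06, adjusted p = 0.168 with an estimated correlation). PAD4, the mutated gene, is a member of this module, which was not tested without it. The values were -2.31 for SARD4, -1.66 for RPP4, -2.03 for XLG2, -1.97 for MYB51, -1.74 for CRK22 (AT4G23300), -4.60 for ACA13, -1.93 for BZIP60, -1.68 for GSTF8 and -2.36 for HSFB1. In photosynthesis 24 of 28 genes had a higher change in pad4 and 1 a lower one, the same adjusted over the list alone (median log2 0.77; camera adjusted p = 1.22e-04, adjusted p = 0.509 with an estimated correlation). In auxin and cell expansion 13 of 17 were higher and 1 lower, and 14 and 1 adjusted over the list alone (median log2 1.88; camera adjusted p = 8.35e-05, adjusted p = 0.234 with an estimated correlation). In abscisic acid and water stress 10 of 19 were higher and 2 lower, the same adjusted over the list alone (median log2 0.85; camera adjusted p = 0.0374, adjusted p = 0.646 with an estimated correlation). That call was also lost without water-treated wild type library 1 (adjusted p = 0.0610; range over camera's alternatives 0.0102 to 0.646). COR15B had 3.27. Epidermis markers were higher in 8 of 10 cases, 8 adjusted over the list alone (median log2 1.33; camera adjusted p = 0.00157, adjusted p = 0.299 with an estimated correlation). CER3 had 1.72. Jasmonate genes (median 0.14, mean -0.0091) and guard cell markers (median -0.090, mean 0.21) did not pass (camera adjusted p = 0.941 and 0.738).

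The wild type and pad4 responses resembled each other weakly gene by gene. Across the 19652 genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.0406 and a Spearman correlation of 0.125. The Pearson correlation ran from -0.00149 to 0.102 with 1 library left out, and was 0.134 for genes with at least 5 CPM in at least 3 libraries. Of the 13608 genes called in wild type 7963 (58.5%) had the same sign in pad4, and over these called genes the Spearman correlation was 0.164. For genes called in wild type the median absolute log2 change was 0.89 in wild type and 0.083 in pad4, and the median ratio of the pad4 to the wild type change was 0.0274. FAMT was the gene called as up in both, where independent lists of rising genes would share 0.346.

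**Figure D2:**
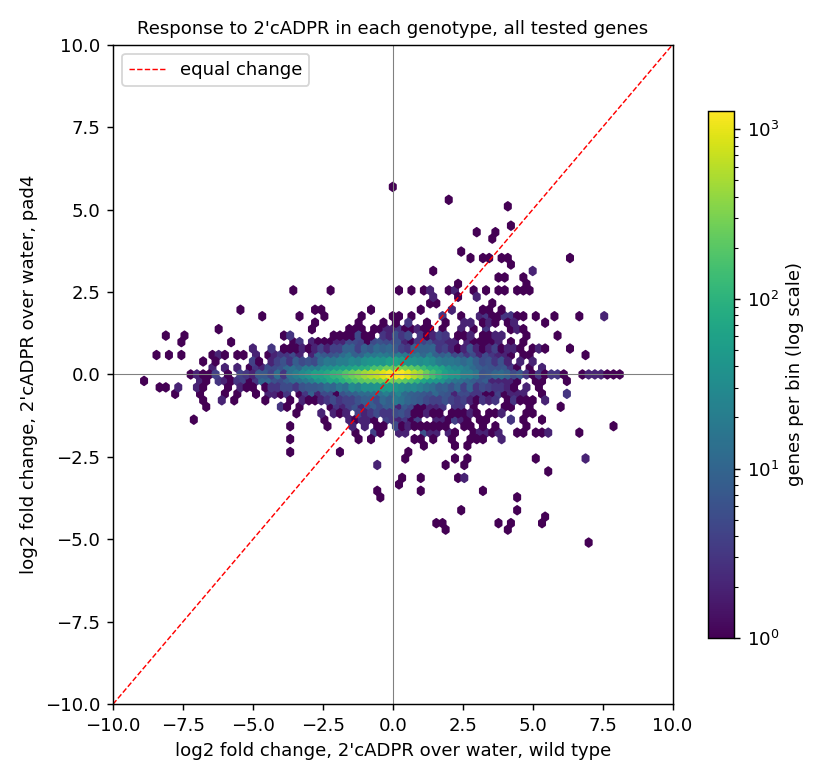
Log2 fold changes after 2'cADPR of the 19652 tested genes in wild type on the x axis and in pad4 on the y axis, as a density of genes, with a dashed red line for equal change. The genes spread along the wild type axis and lie near 0 on the pad4 axis, with a Pearson correlation of 0.0406.

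After water alone, pad4 leaves held less transcript of immune genes than wild type leaves. SARD1 (AT1G73805), a regulator of salicylic acid synthesis, stood at 105 ± 12.9 CPM in wild type and 3.51 ± 0.579 CPM in pad4 (SD, n = 3; log2 -4.90, adjusted p = 1.11e-10). ICS1 stood at 33.3 ± 1.42 and 4.17 ± 1.03 CPM (log2 -2.99, adjusted p = 6.05e-10) and EDS1 at 115 ± 4.04 and 21.3 ± 1.26 CPM (log2 -2.43, adjusted p = 4.66e-10). DMR6 (AT5G24530), a salicylic acid hydroxylase, was lower by the same test, at 231 ± 43.3 and 18.0 ± 3.59 CPM. The log2 differences were -1.004 for SAG101, -0.94 for ADR1, -1.73 for ADR1-L1 and -1.48 for ADR1-L2. The test called 5744 of 19652 genes, 2299 higher and 3445 lower in pad4, of which 216 and 1221 differed at least 2-fold. The share of calls that were higher in pad4 was 40.0%, against 51.6% by limma-trend on the deposited FPKM, 49.8% without scaling factors and 60.8% with trends on GC content and length removed.

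The genes furthest below wild type were WRKY51 (AT5G64810), PR1, ARD3, AIG1 (AT1G33960) and UGT76B1 (AT3G11340). AIG1 stood at 71.2 ± 18.3 CPM in wild type and 0.589 ± 0.416 CPM in pad4 (log2 -6.91), and UGT76B1, a glycosyltransferase that acts in salicylic acid signalling, at 28.2 ± 9.98 and 0.246 ± 0.305 CPM (log2 -6.81, or -8.59 without water-treated pad4 library 2). WRKY51 stood at 7.36 ± 2.59 and 0.0310 ± 0.0137 CPM and ARD3 at 7.63 ± 5.92 and 0.0464 ± 0.0616 CPM, with few reads in pad4. For ARD3 the log2 difference was -7.26, or -6.43 without water-treated wild type library 1. Without water-treated pad4 library 3 a single read was left in pad4, too few for a fold (adjusted p = 5.65e-05), so the ARD3 value rested on both libraries. PR1 stood at 11.8 ± 16.7 and 0.0625 ± 0.108 CPM, and its place here rested on library 1 of each group, which held most of the wild type reads and all of the pad4 reads. Without wild type library 1 the log2 difference was -5.09. The PR1 call was lost with limma-voom (adjusted p over alternatives 8.11e-06 to 0.142). FMO1 was lower in pad4 (log2 -1.92, adjusted p = 0.00518), and -2.68 without water-treated pad4 library 2. The FMO1 call was lost in 3 alternatives (adjusted p over alternatives 2.73e-04 to 0.123). The genes furthest above wild type were PDF1.2a (AT5G44420), a defensin, SEN1 (AT4G35770), MBP1 (AT1G52040), a myrosinase-binding protein, CER4 (AT4G33790), of wax synthesis, and CYP96A12 (AT4G39510). MBP1 stood at 5.77 ± 1.24 and 27.7 ± 8.14 CPM (log2 2.26, adjusted p = 4.06e-06) and SEN1 at 1.82 ± 0.673 and 11.2 ± 6.58 CPM (log2 2.63). CER4 differed by 2.21 and CYP96A12 by 1.92. PDF1.2a stood at 0.578 ± 0.234 and 8.81 ± 11.3 CPM (log2 3.92), and without water-treated pad4 library 2 it was no longer called (log2 2.01, adjusted p = 0.0873; range over alternatives 0.00206 to 0.139).

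Of the 24 lists 15 passed camera's test after water, 11 of them also with an estimated correlation. In salicylic acid synthesis and signalling 20 of 22 genes were lower in pad4, 20 adjusted over the list alone (median log2 -3.49; camera adjusted p = 6.97e-49, adjusted p = 0.00208 with an estimated correlation). The negative regulators were lower in 8 of 10 cases, 8 adjusted over the list alone (median log2 -2.86; camera adjusted p = 1.60e-23, adjusted p = 0.00208 with an estimated correlation), and the EDS1 module in 8 of 9, 8 adjusted over the list alone (median log2 -1.73; camera adjusted p = 8.18e-22, adjusted p = 0.00583 with an estimated correlation). The EDS1 module includes the mutated gene PAD4 and was not tested without it. The salicylic acid and negative regulator lists share genes, so their calls are not independent. WRKY factors were lower in 23 of 31 cases, 23 adjusted over the list alone (median log2 -1.63; camera adjusted p = 2.13e-21, adjusted p = 0.0304 with an estimated correlation). WRKY60 (AT2G25000) stood at 68.7 ± 8.97 and 13.8 ± 1.95 CPM. In pattern-triggered immunity 15 of 26 were lower, 15 adjusted over the list alone (camera adjusted p = 2.96e-12, adjusted p = 0.0444 with an estimated correlation). The median log2 was -1.06, or -0.83 with the gene that had no reads in a group set to its bound. SOBIR1 (AT2G31880) stood at 340.5 ± 52.3 and 58.3 ± 10.4 CPM. In auxin and cell expansion 4 of 17 were higher, 4 adjusted over the list alone (median log2 0.38; camera adjusted p = 0.0402, adjusted p = 0.388 with an estimated correlation). The call was also lost without water-treated wild type library 1 (adjusted p = 0.0546) and with RLE factors (0.0505; range over camera's alternatives 0.0194 to 0.388). Circadian clock genes were higher in 10 of 20 cases and lower in 1, and 11 and 1 adjusted over the list alone (median log2 0.31; camera adjusted p = 0.00554, adjusted p = 0.183 with an estimated correlation). In pathogenesis and systemic acquired resistance 12 of 17 were lower and 1 higher, 12 and 1 adjusted over the list alone (median log2 -2.31; adjusted p = 4.66e-12, or 0.0352 with an estimated correlation). In the TIR-domain receptors 22 of 27 were lower and 1 higher, 22 and 1 adjusted over the list alone (median log2 -0.67; adjusted p = 4.45e-16, or 0.0304 with an estimated correlation). In camalexin and indole glucosinolate synthesis 17 of 22 were lower and 1 higher, 18 and 1 adjusted over the list alone (median log2 -0.73; adjusted p = 9.08e-07, or 0.145 with an estimated correlation). In the cysteine-rich receptor-like kinases 19 of 23 were lower and 2 higher, 20 and 2 adjusted over the list alone (median log2 -1.76; adjusted p = 2.66e-18, or 0.0434 with an estimated correlation). In calcium signalling 10 of 14 were lower, 10 adjusted over the list alone (median log2 -1.33; adjusted p = 5.08e-07, or 0.0444 with an estimated correlation). In endoplasmic reticulum chaperones and secretion 16 of 17 were lower, 16 adjusted over the list alone (median log2 -1.18; adjusted p = 1.33e-25, or 0.0304 with an estimated correlation). In detoxification and oxidative stress 14 of 17 were lower, 14 adjusted over the list alone (median log2 -1.32; adjusted p = 1.12e-07, or 0.116 with an estimated correlation). In the heat shock response 11 of 16 were lower, 11 adjusted over the list alone (median log2 -1.19; adjusted p = 2.20e-07, or 0.0444 with an estimated correlation). Photosynthesis (median 0.028), epidermis (-0.18), guard cell (0.34), vascular (-0.037) and flower, seed and root markers (0.48) did not pass (camera adjusted p = 0.225, 0.457, 0.155, 0.793 and 0.218). The senescence list had a median of 0.076 and a mean of -0.13, and camera's direction was down (adjusted p = 0.886).

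Genes that 2'cADPR raised in wild type and genes lower in pad4 after water overlapped. Of the genes that rose in wild type 2863 were lower in water-treated pad4, where independent lists would share 1194, and 150 were higher, against 797. Of the genes that fell in wild type 1786 were higher in water-treated pad4, against 795, and 173 were lower, against 1192. Both comparisons use the water-treated wild type libraries. Across genes, which are not independent replicates, their log2 values had a Pearson correlation of -0.532 and a covariance of -0.484, while 100 simulations of unchanged groups against the same controls gave a mean correlation of 0.507 and a mean covariance of 0.0321. Subtracting shared controls raises this correlation, so the simulations could not have given a negative value and add no support to it.

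After 2'cADPR the genotypes lay further apart than after water. ICS1 stood at 497 ± 57.7 CPM in wild type and 4.37 ± 0.213 CPM in pad4 (SD, n = 3; log2 -6.83, adjusted p = 6.52e-14), and GSTF8 at 1780.0 ± 62.7 and 118 ± 4.41 CPM (log2 -3.92). NUDT7 stood at 809 ± 56.3 and 25.8 ± 1.52 CPM (log2 -4.97), WRKY46 at 334 ± 38.4 and 1.49 ± 0.411 CPM (log2 -7.80), and IAA3, in the other direction, at 5.60 ± 0.668 and 64.2 ± 3.34 CPM (log2 3.52). The log2 differences were -7.33 for PAD4, -4.11 for EDS1, -2.88 for SAG101, -2.98 for ADR1, -3.34 for ADR1-L1 and -3.21 for ADR1-L2. The test called 14577 of 19652 genes, 7345 higher and 7232 lower in pad4, of which 7795 differed at least 2-fold. With no reads in treated pad4, FMO1 was at least 2234-fold lower than in wild type, ALD1 at least 2071-fold and CHX17 at least 609-fold, against a floor of 3 counts over the group. PR1 stood at 307 ± 48.6 CPM in wild type and ARD3 at 604 ± 73.9 CPM, with few or no reads of either in pad4. With no reads in treated wild type, CSLA01 was at least 263-fold higher in pad4, and TPS03, with a single read there, was higher by a ratio of 872 (95% Poisson interval 156 to 34494). Such floors and intervals cover counting error only. GASA6 was higher by a log2 of 8.26, or 9.37 without treated wild type library 1, IAA29 by 7.52 (adjusted p = 3.12e-07 without library 3, which left no reads in treated wild type), and MYB47 by 7.89.

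Of the 24 lists 16 passed camera's test between genotypes after 2'cADPR, 3 of them also with an estimated correlation, which were the EDS1 module, salicylic acid and the negative regulators. The salicylic acid and negative regulator lists share DMR6, DLO1, NPR3 and NPR4, so these calls are not independent. In the EDS1 module all 9 of 9 genes were lower in pad4, 9 adjusted over the list alone (median log2 -3.34; camera adjusted p = 1.95e-11, adjusted p = 0.0477 with an estimated correlation). These 9 include PAD4, the mutated gene itself, and the module was not tested without it. In salicylic acid synthesis and signalling 21 of 22 were lower, 21 adjusted over the list alone (median log2 -6.63; camera adjusted p = 1.46e-19, adjusted p = 0.0477 with an estimated correlation). SARD1 stood at 787 ± 73.6 CPM in wild type and 3.65 ± 0.871 CPM in pad4. Negative regulators were lower in 9 of 10 cases and higher in 1, the same adjusted over the list alone (median log2 -4.86; camera adjusted p = 2.49e-10, adjusted p = 0.0477 with an estimated correlation). WRKY factors were lower in 31 of 31 cases, 31 adjusted over the list alone (median log2 -3.24; camera adjusted p = 1.72e-11, adjusted p = 0.128 with an estimated correlation). Photosynthesis genes were higher in pad4 in 24 of 28 cases and lower in 1, the same adjusted over the list alone (median log2 0.79; camera adjusted p = 4.14e-04, adjusted p = 0.508 with an estimated correlation), and genes of auxin and cell expansion in 14 of 17 and 1, also the same adjusted over the list alone (median log2 2.29; camera adjusted p = 4.14e-04, adjusted p = 0.184 with an estimated correlation). Epidermis markers were higher in 9 of 10 cases, 9 adjusted over the list alone (median log2 1.15; camera adjusted p = 0.0299, adjusted p = 0.448 with an estimated correlation). CER3 stood at 36.1 ± 2.70 and 114 ± 17.2 CPM.

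**Figure D3:**
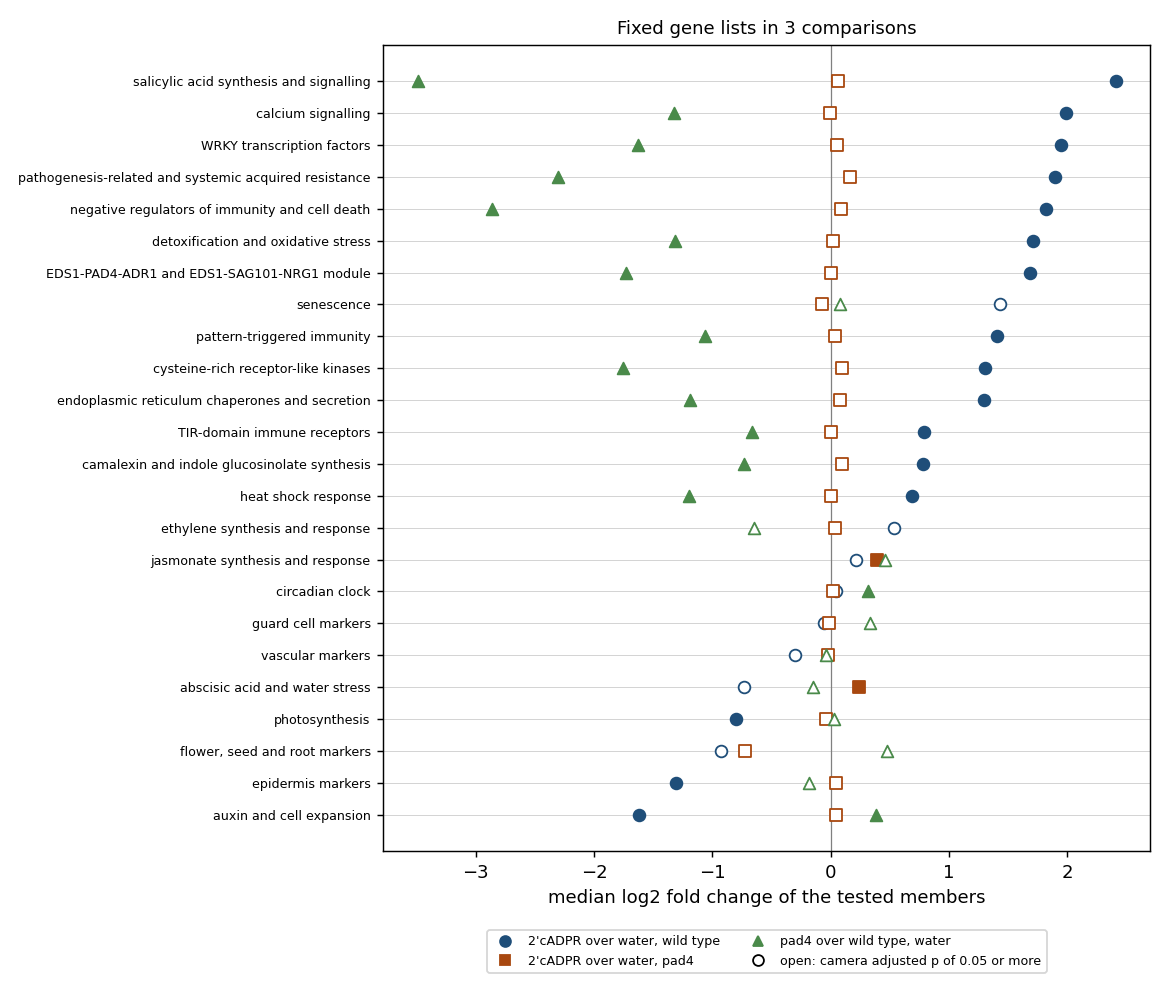
Median log2 fold change of the 24 gene lists after 2'cADPR in wild type (circles) and in pad4 (squares), and of pad4 over wild type after water (triangles), with open symbols where camera's adjusted p was 0.05 or more. The salicylic acid list lies at 2.41 in wild type, 0.062 in pad4 and -3.49 between genotypes after water.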

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

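The tests of a low baseline, of uptake, of a batch or handling shared by both genotypes, of the windows around PAD4 and of the shared water-treated wild type libraries, and the runs without scaling factors, thinned, and with GC and length trends removed, were chosen only after the results were seen. The responses to 2'cADPR differed between wild type and pad4 by the interaction test for 11326 genes, and by camera with its preset correlation for the lists below. The interaction is the log2 change in pad4 minus that in wild type, and the values are list medians. They were -1.69 for the EDS1 module, -2.54 for salicylic acid, -1.45 for pathogenesis and systemic acquired resistance, -0.79 for TIR-domain receptors, -1.46 for pattern-triggered immunity, -1.89 for WRKY factors and -0.77 for camalexin and indole glucosinolates. They were -1.198 for cysteine-rich receptor-like kinases, -1.51 for calcium signalling, -1.67 for negative regulators, -1.24 for endoplasmic reticulum chaperones, -1.68 for detoxification and -0.51 for heat shock. Positive medians were 0.85 for abscisic acid and water stress, 0.77 for photosynthesis, 1.88 for auxin and cell expansion and 1.33 for epidermis markers. With an estimated correlation 0 of the 24 lists passed, so how far these list calls go beyond the correlation between their genes stays open.

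For single genes the log2 interaction was -3.18 for PAD4, -1.69 for EDS1, -1.87 for SAG101, -2.04 for ADR1, -1.60 for ADR1-L1, -1.73 for ADR1-L2, -3.84 for ICS1, -2.31 for SARD4 and -3.02 for NPR3. It was -1.66 for RPP4, -2.03 for XLG2, -3.73 for WRKY46, -1.97 for MYB51, -1.74 for CRK22, -4.60 for ACA13, -6.33 for ABCB11, -1.93 for BZIP60, -1.68 for GSTF8 and -2.36 for HSFB1. Genes that fell in wild type had 3.27 for COR15B, 2.17 for RBCS2B, 3.08 for IAA3, 1.72 for CER3, 7.12 for IAA29, 6.79 for HMT3 and 6.76 for MYB47. Without treated wild type library 3, which held its only reads in that group, IAA29 had an adjusted p of 5.24e-06, and without treated wild type library 1 HMT3 had 2.80e-08. For genes with too few reads in a group for a fold, the adjusted p of the interaction was 2.65e-05 for CSLA01, 6.28e-05 for TPS03, 1.22e-06 for FMO1, 0.00831 for ALD1, 0.00748 for CHX17 and 0.00471 for CML43. Without water-treated pad4 library 1 the adjusted p was 0.9998 for ALD1 and 0.267 for CHX17, and without library 3 it was 0.9998 for CML43. In water-treated pad4 ALD1 held only 2 reads, CHX17 10 and CML43 6 over the group. These lost calls thus bear on the change within pad4, not on the rises in wild type.

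In wild type 13608 of 19652 tested genes changed after 2'cADPR. The tables argue against the choice of scaling factors, against depth and against GC content and gene length as the whole cause. The count was 13517 at its lowest under RLE or no scaling factors and 13517 with every library thinned to the smallest total. With trends on GC content and length removed it was 13753. All these scalings are relative, so none could show a shift in the total amount of messenger RNA. Of the 10 splits of the 6 libraries, 1, the real one, called 13608 genes and the highest other 0, and 10 splits are too few for a share under 0.05. For the interaction, 4 of 100 draws from 200 regroupings called as many genes as the real 11326, the real one included; all 7 other draws that kept the treated libraries parted by genotype called 11022 to 12655, and the 92 draws that did not called 0, so the count followed the contrast between the treated genotypes. A batch or handling shared by the treated leaves of both genotypes is argued against as the whole cause, since over the genes called in wild type the pad4 change was a median of 0.0274 of the wild type change (upper quartile 0.118). A response to 2'cADPR is a candidate explanation, while handling that touched wild type alone or acts through PAD4 may also add to the pattern and was not tested, since the labels name no batch.

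In pad4 edgeR called 1 gene after 2'cADPR, with 992 genes at an unadjusted p under 0.05, while DESeq2 called 26. With only the pad4 groups in the fit, 1335 of 18870 genes were under 0.05. A larger spread between pad4 libraries is argued against, since the median SD within pad4 groups over that within wild type groups was 0.836 (0.128 against 0.153). A low baseline that hides the response is argued against too: among 10552 genes called in wild type with at least 5 CPM in water-treated pad4, the median ratio of the pad4 to the wild type change was 0.0306, and 158 genes (1.497%) had a ratio of 0.5 or more. That pad4 leaves took up less compound cannot be told apart from a need for PAD4. The genes called in pad4 numbered 1, and no measure of uptake was analysed here. The interaction at 11326 genes does not separate these explanations, since either could give it. Of the 10 splits of the pad4 libraries 4 called as many genes as the real 1, the highest other called 10, and 10 splits are too few for a share under 0.05.

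Differences between water-treated pad4 and wild type ran opposite to the wild type response to 2'cADPR on balance. The correlation across genes was -0.532, while 100 simulations of unchanged groups against the shared water-treated wild type libraries gave 0.482 to 0.531. Subtracting the same controls can only raise this correlation, so the simulations could not have given the opposite movement and add no support to it. Water-treated wild type library 1 alone is argued against, since the correlation without it was -0.446. For a chromosome segment carried with the mutation the values do not decide: among genes with an unadjusted p of 0.05 or more for 2'cADPR in both genotypes 12 of 127 within 1 Mb of PAD4 (9.45%) and 461 of 5273 elsewhere (8.74%) were called between genotypes after both treatments in the same direction, a ratio of 1.08 (95% interval 0.569 to 1.82; exact Fisher p = 0.750, two-sided), while the 1 Mb window that holds PAD4 had 11 of 72 (15.3%), only rank 9 of 119 windows by share, and the window before it 0 of 52. Of the 10 splits 1, the real one, called 5744 genes between genotypes after water and the highest other 0; after 2'cADPR the numbers were 1, 14577 and 0, and 10 splits are too few for a share under 0.05. A basal activity of the PAD4 pathway in water-treated wild type leaves is a candidate explanation, and separate growth or handling of the genotypes, on which the labels say nothing, stays open as well, as does a short segment around PAD4.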

How the results depend on the processing

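Runs without scaling factors, thinned to the smallest total, with GC and length trends removed, and camera without water-treated wild type library 1 were chosen only after the results were seen. With a log2 fold change of at least 1 asked as well, the counts were 6002 in wild type, 5336 for the interaction, 1437 between genotypes after water and 7795 after 2'cADPR, by construction smaller. In pad4 the count of 1 became 26 with the DESeq2 Wald test, 2 with only the compared groups in the fit and 3 with limma-trend on log2 of FPKM with 1 added and no filter; FAMT was among the genes in each of these, and the cause of the increase was not tested. Leaving out 1 library at a time gave 12833 to 13382 genes in wild type, 1 to 3 in pad4 (2 without water-treated library 1 and 3 without water-treated library 3), 10653 to 11418 for the interaction, 4675 to 5007 between genotypes after water and 13950 to 14378 after 2'cADPR. The correlation between the wild type and pad4 responses was 0.134 with at least 5 CPM in at least 3 libraries, and -0.00149 (without treated pad4 library 2) to 0.102 (without water-treated pad4 library 2) leaving out 1 library, against 0.0406. PAD4's difference in log2 ran from -5.92 to -5.28 leaving out 1 library and was -5.34 from FPKM. Camera with the correlation estimated called 0 lists in wild type, 0 in pad4, 0 for the interaction and 3 between genotypes after 2'cADPR. Fry called 22 lists in wild type, 0 in pad4, 21 for the interaction, 18 between genotypes after water and 24 after 2'cADPR. In the same order fry for either direction called 23, 0, 23, 21 and 24. Across the 24 lists and all comparisons 681 of 792 results of alternatives fell on the same side of the threshold, 59 no longer passed and 52 newly passed, of which estimated correlation accounted for 52 lost, fry for 21 gained and 2 lost, and fry for either direction for 27 and 2. Without water-treated wild type library 1 camera lost the abscisic acid list for the interaction (adjusted p = 0.0610, range over camera's alternatives 0.0102 to 0.646) and the auxin list between genotypes after water (0.0546, and 0.0505 with RLE factors, range 0.0194 to 0.388). It gained the senescence list for the interaction (0.0266, and 0.0465 with the replicate block and 0.0363 with no filter, range 0.0266 to 0.234). For named genes 7355 of 7395 values were called as before, 36 were no longer called, 4 were newly called and 0 called values changed sign, with 17 of 366 named results touched. The call of FMO1 between genotypes after water had adjusted p from 2.73e-04 to 0.123 over its alternatives. No sign was seen that replicate numbers mark shared samples. After group means were removed, libraries of the same number had a correlation of at most 0.0855, and those of different numbers of at most 0.168. Only 2 of 12 libraries resembled their own number most. With 3 libraries per group a weak shared batch could be missed. With the number as a block the counts were 13468, 1, 11218, 5580 and 14464 in the order above. Thinning, which gave 13517 genes in wild type, tested unequal totals only, and deeper sequencing was not tested. With 3 libraries per group simulated changes of 2-fold were found for 76% of genes in the pad4 comparison and 72% for the interaction, and smaller ones less often. These shares hold for the simulated number of changed genes. The data had 1 call in pad4 and 11326 for the interaction, so the shares found there may differ.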

Other observations

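The gene families, the single genes and, for the jasmonate list, the medians with libraries left out or regrouped were chosen only after the results were seen. Families named by the product text of the reference, 182 of them with at least 10 tested genes, were tested as well. In wild type after 2'cADPR, 10 of 10 genes for SPFH-domain membrane proteins rose (median log2 1.49), 9 of 10 genes of the p24 family, which carries cargo between endoplasmic reticulum and Golgi, rose (median 1.11), and 39 of 49 TIR-NBS-LRR receptor genes rose (median 0.92, 10 of them in the lists above). Pectin lyase-like genes of the cell wall fell in 29 of 39 cases (median -1.54), SAUR-like auxin-responsive genes in 36 of 55 (median -2.43) and NPH3 genes of light responses in 23 of 28 (median -1.04). Camera called 16 families in wild type, 7 up and 9 down, 3 in pad4 and 13 between genotypes after water. With an estimated correlation it called 0 in wild type (adjusted p = 0.674 for the SPFH family), 0 in pad4 (lowest adjusted p = 0.997) and 0 between genotypes after water.

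Of 5400 genes with an unadjusted p of 0.05 or more for 2'cADPR in both genotypes, 473 were called between genotypes after water and after 2'cADPR in the same direction. PCC1 (AT3G22231), a small membrane-associated protein gene, stood at a mean of 1039 CPM in water-treated wild type and 68.1 CPM in water-treated pad4 (adjusted p = 1.56e-05). The receptor-like protein genes RLP41 (AT3G25010) and RLP39 (AT3G24900) stood at 38.5 and 2.42 CPM in wild type and at 2.04 and 0.0465 CPM in pad4. AT3G53065, on chromosome 3 from 19672726 to 19673567, near PAD4, was listed at 0 in all pad4 libraries and at 0.346 CPM in water-treated wild type.

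In pad4 the 26 genes that DESeq2 called after 2'cADPR, 23 up and 3 down, were not tested for enrichment of any group. OPCL1 (AT1G20510) from 39.6 to 53.1 CPM, OPR3 (AT2G06050) from 92.1 to 115 CPM, JAZ2 (AT1G74950) from 29.6 to 38.9 CPM, JAZ6 (AT1G72450) from 42.3 to 54.5 CPM and MYC2 from 124 to 176 CPM, all of jasmonate synthesis or response, were among them, along with CLH1 (AT1G19670) from 197 to 291 CPM. EdgeR's adjusted p for these were 0.227, 0.463, 0.449, 0.449, 0.227 and 0.208. PDF1.2b (AT2G26020), a defensin gene like PDF1.2a of the jasmonate list, was also among the 26 but fell, from 3.35 to 0.502 CPM (edgeR adjusted p = 0.381). In wild type CLH1, JAZ6 and MYC2 fell, by log2 values of -1.85, -1.07 and -0.29, OPCL1 rose by 0.86, and JAZ2 and OPR3 were not called (adjusted p = 0.351 and 0.0545). For the jasmonate list in pad4 the median log2 was 0.39 with all libraries, 0.24 at its lowest with 1 pad4 library left out (water-treated library 2) and 0.63 at its highest (water-treated library 1), so how far a single library carries it stays open. That list did not pass with an estimated correlation (adjusted p = 0.185), with fry (0.369) or with fry for either direction (0.0522). Of the 10 splits of the pad4 libraries 2 gave an absolute median of log2 differences as large as the real 0.43, with a highest other of 0.48, and 10 splits are too few for a share under 0.05.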
